A study of Mus musculus with 14 samples.

How the data were processed

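H3K27me3 ChIP-seq was available as 1 region list per library for 2 control and 2 Phf19 KO libraries, and MARS-Seq as 1 count table per plate for 4 plates. The submitters' processing notes name the genome build mm9, besides dm3, and the tools Bowtie and TopHat for the ChIP-seq, and GRCm38.p4 and FastQC for the MARS-Seq; versions are not given in the sources used here. Region names and track lines show lists written by MACS per library, per the file headers. The caller's version, threshold and control library are not given in the sources used here. Each region has a score deposited by the authors, whose layout is that of a caller writing a scaled logarithm of a p-value, and no score is below 50. The score was used only to describe, rank or filter regions within a list. The MARS-Seq tables hold whole-number counts per gene and cell, deposited by the authors without normalization, and the labels name the protocol, in which counts are of UMIs.

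Samples were grouped by their titles. The plates have no genotype in the labels and are given singly, with ranges and medians. The cell names in the table headers carry a WT or KO prefix, and this split within plates was used for a comparison that was not in the design fixed before the data were examined. WT and KO cells occupy separate ranges of well numbers in every plate, so genotype and well position are confounded. Whether the WT cells are the floxed controls of the ChIP-seq is not stated. The model for this comparison was chosen after the tables were seen, and fits with and without the plate as a block were first run together. The block was set as the main model only after both counts of called genes were known, 6 with it and 0 without it. The reason given for it is that both genotypes of a plate share a plate and a table, and the count without it stands beside it in the report.

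Regions were compared with Python 3.11.15, scipy 1.17.1 and bedtools 2.31.1. Lists were merged into a union, and a union region was called in a library when it overlapped a region of that library by 1 bp or more. Overlap of pairs was measured by the Jaccard index of covered bases and by 100 random placements within chromosomes, taking the highest region end as chromosome length. Values per library were compared by two-sided exact permutation tests. Regions were not assigned to genes, because the reference tables at hand belong to another build, so the 3 planned results on promoters were not run. Chosen by a rule fixed before the data were examined, the 5 widest union regions of each class are described.

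Gene IDs were paired with symbols for 25714 of the 25832 IDs in the 4 tables, and a gene missing from a table was taken as 0 there. Cells with at least 500 UMIs were kept, without doublet calling. Counts were summed per plate and genotype and tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Where a gene's spread lay below that of Poisson counts, edgeR bounds the p-value by a Poisson test, and such a standard error is too small. DESeq2 1.42.0 was an alternative. The 22 gene lists were written before the data were examined, and 16 with 3 or more tested members were tested with camera (preset and estimated correlation) and fry of limma 3.58.1. The model was tested on simulated counts of 6541 genes, 200 of them changed, where 7 of 121 calls were false. Genes named by rule were PRC2 subunits, up to 5 members of every other list by mean counts scaled to a common total (CPM), the 10 highest genes outside ribosomal and mitochondrial genes and 5 leading genes per cluster.

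Cells were clustered with scanpy 1.11.5 on 1500 variable genes, 15 principal components and 15 neighbours by the Leiden method at resolution 1. Relations between lists used cells thinned to 1500 UMIs. Intervals are exact (Clopper-Pearson) at 95% and cover counting error only. Alternatives were stricter region lists, merging within 1000 or 5000 bp, a minimum width of 500 bp, autosomes alone, a larger overlap, each replicate left out, other cell filters, scalings, resolutions and models.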

Results

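Haematopoietic stem cells (HSCs) were taken from mouse bone marrow of floxed control animals and of animals lacking Phf19, a Polycomb-associated protein that binds the complex depositing trimethylation of lysine 27 on histone H3 (H3K27me3, a mark of repressed chromatin). The series holds 14 samples, of which 8 have data used here. H3K27me3 chromatin immunoprecipitation with sequencing (ChIP-seq) of CD150-positive cells gave a list of marked regions for each of 2 control and 2 KO libraries. MARS-Seq, a plate-based single-cell RNA method that counts molecules by unique molecular identifiers (UMIs), gave counts for 4 plates of cells labelled CD150-positive CD48-negative. The bulk RNA-seq and chromatin accessibility samples were not analysed here. The labels give no genotype for the plates, but the cell names in the count tables carry the prefix WT or KO, with 96 wells of each per plate. Nothing in the labels says whether replicates or plates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

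The first comparison asked how the regions marked by H3K27me3 differed between KO and control HSCs. The KO lists held more regions than the control lists, with 6036 and 4607 regions in KO replicates 1 and 2 against 4089 and 917 in control replicates 1 and 2. The mean was 5321.5 ± 1010.5 regions in KO and 2503 ± 2243 in control (SD, n = 2 each), a ratio of 2.13, and the two-sided exact permutation test gave p = 0.333, the smallest that 2 libraries against 2 allow. Without control replicate 2, the shortest list, the ratio was 1.30, and without control replicate 1 it was 5.80. Read depths of these libraries are unknown here, so the lists cannot be set on a common depth.

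The regions covered 9.80 Mb and 1.5 Mb in control replicates 1 and 2, and 12.3 Mb and 6.77 Mb in KO replicates 1 and 2. The KO to control ratio of mean covered length was 1.69 (exact permutation p = 0.667), and it was 0.972 without control replicate 2, so the direction of this difference rested on that library. Median region width was 2149 bp and 1471 bp in the control lists and 1664 bp and 1217 bp in the KO lists, a ratio of means of 0.796 (exact permutation p = 0.667). Neither difference was larger than the spread between replicates.

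**Figure D1:**
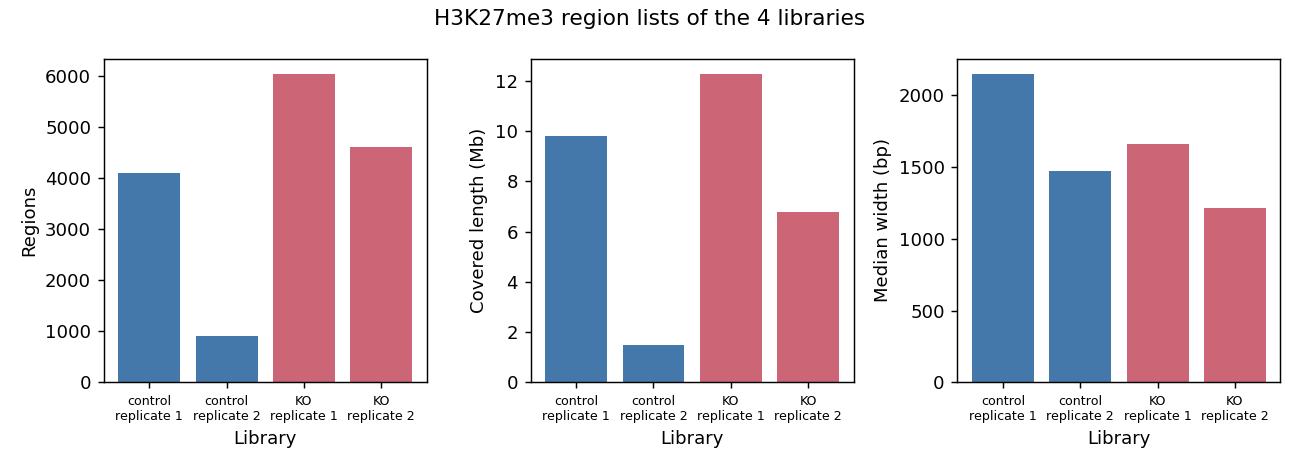
Bars show the number of H3K27me3 regions, their covered length in Mb and their median width in bp for each of the 4 libraries, control in blue and KO in red. Control replicate 2 has 917 regions, against 4089 to 6036 in the other libraries.

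The 4 lists merged into 9361 regions, of which 488 were present in all 4 lists and 5636 in a single list. Regions found in both KO lists and neither control list numbered 462, and regions found in both control lists and neither KO list numbered 16. Regions shared by both replicate 1 lists and absent from both replicate 2 lists numbered 980, more than the KO-specific ones, with 59 in the mirror class. When each list was reduced to its 917 highest regions by the authors' score, an alternative chosen after the data were seen, the counts were 92 KO-specific and 67 control-specific regions. Pairs of libraries overlapped unevenly. The Jaccard index of covered bases was 0.430 for control 1 with KO 1, 0.263 for control 1 with KO 2, 0.261 for both KO libraries, 0.131 for control 2 with KO 2, 0.0995 for both control libraries and 0.0828 for control 2 with KO 1. The short list of control 2 limits each of its values. At equal list lengths the index was 0.324 for control 1 with KO 1, 0.178 for control 2 with KO 2, 0.161 for both KO libraries, 0.146 for control 1 with KO 2, 0.134 for both control libraries and 0.111 for control 2 with KO 1. Every pair overlapped more than random placement, for example 619 of the control 1 regions lay in control 2 regions against at most 16 in 100 random placements.

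The widest regions of each class are given in mm9 coordinates without gene names, since no annotation of that build was used here. The widest region present in all lists spanned 7235 bp on chromosome 10 from 79816050 to 79823284, with authors' scores of 93.0 and 77.5 in control and 66.2 and 122 in KO replicates 1 and 2. The widest region of both KO lists and neither control list spanned 7591 bp on chromosome 19 from 44907371 to 44914961, with scores of 60.1 and 50.8, close to the lowest score of 50 in these lists. The other wide KO-specific regions lay on chromosomes 9, 11, 7 and 2 and spanned 6826 to 7530 bp. Their scores were 59.0, 50.4, 90.7 and 51.2 in KO replicate 1 and 95.4, 139, 56.4 and 107 in KO replicate 2. The widest region of both control lists and neither KO list spanned 5307 bp on chromosome 2 from 17949550 to 17954856, with scores of 50.1 and 61.1.

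**Figure D2:**
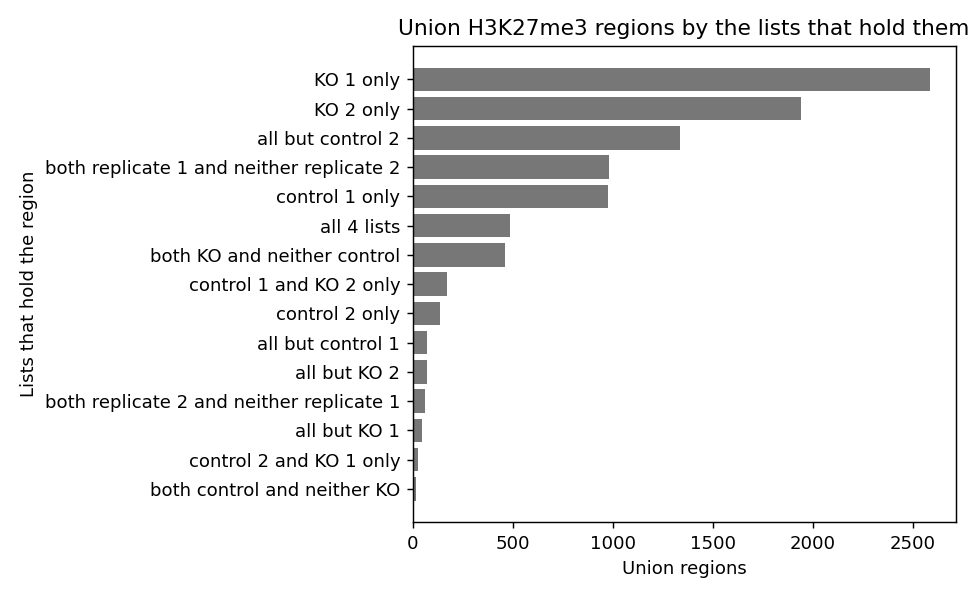
Bars show how many of the 9361 union regions are held by each combination of the 4 lists. The class of both replicate 1 lists (980) exceeds the class of both KO lists (462).

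The X chromosome, which carries broad H3K27me3 when inactive in female cells, held 45 and 21 regions in control replicates 1 and 2 and 105 and 190 in KO replicates 1 and 2. Its share of covered length was 0.951% ± 0.241 in control and 1.80% ± 0.833 in KO (SD, n = 2 each; exact permutation p = 0.333, the smallest possible). The difference of 0.847 percentage points was 0.258 without KO replicate 2, 1.44 without KO replicate 1 and 0.234 among the higher-scoring regions of each list. The sex of the animals is not given in the labels.

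The second comparison asked which transcripts differed between KO and WT cells of the same plates. It was added after the count tables were seen, and genotype cannot be told apart from the range of well numbers. The plates differed in their transcripts, with Flt3, a receptor of multipotent and lymphoid progenitors, at 7.5, 19.8, 368 and 163 CPM in 350W to 353W. Of 768 wells, 716 had at least 500 UMIs, and these cells gave totals of 220821 to 510791 UMIs per plate and genotype. Fewer KO wells reached that minimum: 49 KO and 3 WT wells were left out. Median UMIs per kept cell were lower in KO than in WT cells in 4 of 4 plates, at 0.725 to 0.896 of the WT value (two-sided exact sign-flip p = 0.125, the smallest that 4 plates allow, for 1 of 5 measures compared). Phf19 itself had 1, 0, 0 and 5 UMIs in WT cells and 0, 2, 1 and 0 UMIs in KO cells of plates 350W, 351W, 352W and 353W. A 3' tag need not lie in the deleted part, so this count checks no label.

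Of 6541 genes tested with edgeR's quasi-likelihood test and the plate as a block, 2 were higher and 4 lower in KO cells at a Benjamini-Hochberg adjusted p below 0.05. All 6 lie outside the rule for named genes except Ighm, and were chosen after their values were seen. Bach2, a transcription factor of lymphoid development, fell by 3.35 on the log2 scale (SE 0.238, edgeR adjusted p = 4.63e-07) and was lower in 4 of 4 plates. Its summed counts were 117, 110, 60 and 137 in WT cells and 7, 9, 1 and 14 in KO cells of plates 350W, 351W, 352W and 353W. The WT counts were spread over many wells, with a UMI in 23.2% to 49.5% of WT cells against 1.35% to 15% of KO cells, and at most 8 UMIs in a single WT well. Top1, which encodes a DNA topoisomerase, had a log2 fold change of -1.35 (SE 0.243, edgeR adjusted p = 0.0425), and its call was lost without any 1 of the 4 plates (edgeR adjusted p of 0.0853 to 0.523, log2 fold changes of -1.45 to -1.28) and with no filter on cells (0.0501). Rpl30, a ribosomal protein gene, rose by 0.76 on the log2 scale (SE 0.0881, edgeR adjusted p = 4.05e-04), and the predicted gene Gm10288 by 0.60 (edgeR adjusted p = 0.0444), whose call was lost without 350W, 351W or 353W. With log2 fold changes of 0.54 to 0.64 over the alternatives, the Gm10288 call was also lost with library totals (edgeR adjusted p = 0.0563), with no filter on cells (0.0582) and after thinning to equal totals (0.0721). The share of UMIs in ribosomal protein genes was also higher in KO cells in 4 of 4 plates, with 13.7% to 14.8% against 12.6% to 14.0% in WT cells. The two-sided exact sign-flip p was 0.125, the smallest possible, for 1 of 5 measures, and the difference in 350W was 0.134 percentage points. Ribosomal protein genes and Gm10288 can share reads with near-identical copies, so both are uncertain.

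The immunoglobulin transcripts Igkv14-126 and Ighm had log2 fold changes of -2.09 and -1.10 (edgeR adjusted p = 0.00174 and 0.0246). A single WT well of plate 353W held 186 of the 221 Igkv14-126 counts and 526 of the 798 Ighm counts of WT cells there. Without the wells of over 100 immunoglobulin UMIs, Ighm had a log2 fold change of -0.08 (edgeR adjusted p = 0.993), Igkv14-126 had too few counts to be tested, and 2 genes were called, Bach2 and Rpl30. Top1 and Gm10288 kept log2 fold changes of -1.33 and 0.59 there, at an edgeR adjusted p of 0.0853 each. The model without the plate block called no gene, with an adjusted p of 0.08 for Bach2 and 86 genes at an unadjusted p below 0.05, against 398 with the block. DESeq2 called 1 gene, Bach2, and 63 at an unadjusted p below 0.05. By chance a share of 0.05 of the 6541 tested genes would pass that threshold, which 398 is somewhat above and 86 and 63 are below.

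**Figure D3:**
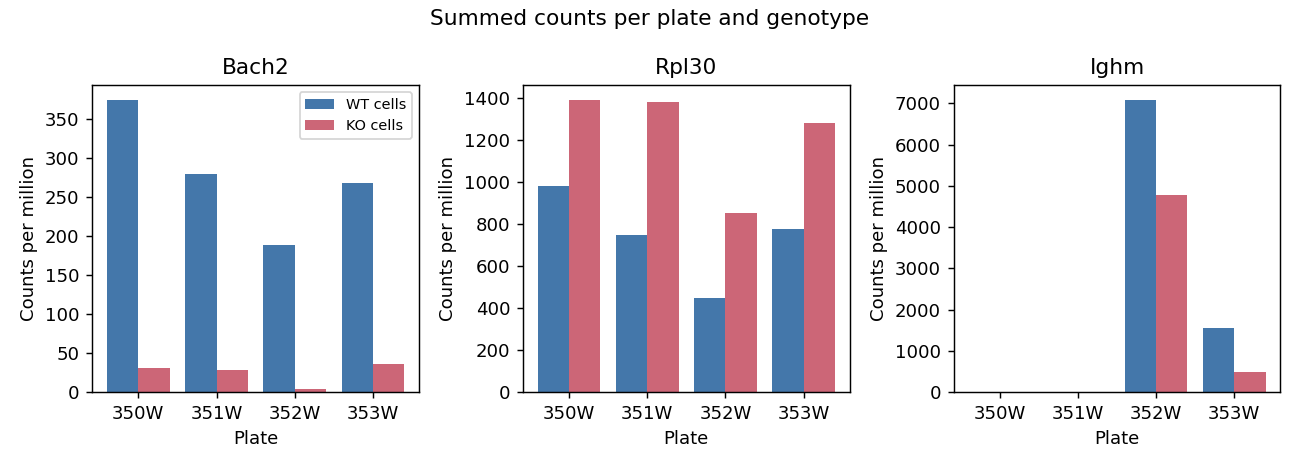
Bars show summed counts per plate and genotype, scaled to a common total (CPM), of Bach2, Rpl30 and Ighm in WT (blue) and KO (red) cells of plates 350W to 353W. Bach2 lies between 189 and 375 in WT cells and between 4.53 and 36.6 in KO cells.

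None of the 16 fixed gene lists with enough tested members was called as a set. The lowest adjusted camera p was 0.291, for the G2/M phase list, with an adjusted p of 0.821 with an estimated correlation, and no list passed by fry. Among subunits of the Polycomb repressive complex 2 (PRC2), 9 were tested and none was called over all genes or adjusted over the list alone. Rbbp7 had a log2 fold change of -0.30 (SE 0.14), Suz12 of 0.59 (SE 0.34), Ezh2 of -0.19 (SE 0.35) and Eed of 0.23 (SE 0.27). Of 19 tested HSC markers none was called, with values of -0.14 for Hlf (SE 0.14), -0.03 for Kit (SE 0.15) and -0.22 for Mecom (SE 0.18). None was called over all genes or adjusted over the list alone among 10 tested PRC1 subunits, 6 quiescence genes, 12 S phase genes, 9 G2/M phase genes, 6 megakaryocyte genes, 6 interferon genes, 10 lineage transcription factors and 3 Hox genes. The same held for 2 neutrophil genes, 3 T and NK cell genes, 1 mast cell gene, 1 endothelial gene, 1 developmental transcription factor and 2 sex-linked genes, while no H3K27 demethylase had enough counts to be tested. Adjusted over the list alone, 1 gene passed in each of the erythroid, monocyte and dendritic, lymphoid and B cell, immediate early and housekeeping lists. These were Hbb-bt, Cd74, Ighm, Jun and B2m, all with lower values in KO cells, and of these Ighm alone passed over all genes. On simulated counts for this comparison, 12% of genes changed 1.5-fold, 50% of those changed 2-fold, 88% of those changed 4-fold and 78% of those changed 8-fold were recovered, so most changes of 1.5-fold were not detectable at this depth.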

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

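The test without wells of high immunoglobulin counts was chosen after the result was seen.

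Immunoglobulin UMIs appeared in wells that the comparisons left out for having under 500 UMIs, with 232 in plate 352W and 17 in plate 353W, above the 3 counts that a count of 0 allows. Among kept cells, 100% of cells in plate 352W and 98.3% in plate 353W had an immunoglobulin UMI. The share of UMIs was 2.99% in left-out wells against 1.62% in kept wells of plate 352W, and 0.374% against 0.263% in plate 353W. The lowest ratio was thus 1.42, and the exact 95% interval of 0.218% to 0.599% for the left-out wells of 353W holds the kept value. However, a single WT well held 1317 of the 2352 kept immunoglobulin UMIs of 353W. Of the 17 left-out wells there, 16 were KO, and kept KO cells were at 0.114%, below that interval. RNA or reads shared between wells may therefore account for the spread over wells, although cells holding little other RNA stay open. The lower Ighm in KO cells went with a few wells, since without wells of over 100 immunoglobulin UMIs the log2 fold change was -0.0841 (edgeR adjusted p = 0.993). The wells left out were 4 WT and 3 KO wells of 352W and 1 WT well of 353W. They were picked by counts that include Ighm itself.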

How the results depend on the processing

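The models, filters and left-out plates of the KO against WT cell comparison, and equal list lengths, were chosen after seeing the data. Of 137 alternatives for the main results, 117 kept their direction (region ratios, differences and overlaps, whose size could still move far), stayed within 1.5 times (counts of regions, genes and clusters) or within the interval of the main value (levels, depths and correlations). The ratio of region numbers was 1.30 to 5.80 and the X share difference 0.258 to 1.44 points without a replicate (0.234 among higher-scoring regions). The KO to control ratio of covered length reversed to 0.972 without control replicate 2 and was 6.34 without control replicate 1. Regions of both KO and neither control list numbered 92 at equal list lengths and 535 to 1796 without a control replicate. Regions of both control and neither KO list numbered 9 among the higher-scoring regions of each list, 67 at equal list lengths and 61 to 87 without a KO replicate; asking fewer lists to lack a region raises the count by construction. With the replicate number as a block, 3526.5 regions on average were in the KO and not the control list of a number, and 728 the reverse. Number, covered length and width gave block ratios of 2.72, 2.38 and 0.800, as means on the log scale, because a mean of plain differences equals the main value, as the 0.847 points of the X share do. With 2 pairs the numbers are not shown to pair the samples. The called genes numbered 0 with no replicate block, 27 with no gene filter, 3 with no filter on cells, 2 without wells of over 100 immunoglobulin UMIs, 1 with DESeq2, and 2 to 12 without a plate (12 without 352W, 2 without 353W); the cause was not tested. Bach2 was called in 11 of 12 alternatives, with log2 fold changes of -3.63 to -3.17 and adjusted p from 8.00e-40 to 0.08. Averaging CPM over cells moved the median over plates of HSC markers to 4235, S phase to 888, G2/M phase to 635 and the lymphoid and B cell list to 959. Promoter alternatives were not run. Read depth behind the region lists is unknown.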

Other observations

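The tests of recurring wells, of a steady trend over wells, of lymphoid cells, the short control list and the replicate numbers were chosen after the results were seen. The 4 plates carry one sort in the labels, CD150-positive CD48-negative, and differed in their transcripts. Mpo, a granule enzyme of myeloid progenitors, was at 0 CPM (counts scaled to a common total) in plates 350W and 351W, 186 in 352W and 194 in 353W. Among other members of the neutrophil list, Ctsg was at 0, 0, 53.9 and 56.0 in plates 350W to 353W. Cebpa was at 0, 0, 59.4 and 7.84. Prtn3, at 217, 188, 258 and 272, and Csf3r, at 0, 304, 11.1 and 23.5, did not share this pattern. Cd48, the marker excluded by the sort, was at 1.87, 0, 206 and 39.2, and Flt3, a receptor of multipotent and lymphoid progenitors, at 7.5, 19.8, 368 and 163. Slamf1, which encodes the CD150 that the sort selects, was at 9.37, 29.7, 1.86 and 0, from 5, 21, 1 and 0 UMIs. Cd48 and Slamf1 were chosen after their values were seen. Vwf, a gene of platelet-biased stem cells, was at 510, 46.7, 5.57 and 16.8. The HSC marker list ranged from 2912 to 4897 CPM with a median of 3974, the G2/M phase list from 287 to 1564 (median 807) and the S phase list from 695 to 1605 (median 1001.1). The lymphoid and B cell list ranged from 157 to 7099, with Ighm at 6141 in 352W, and the megakaryocyte list from 273 to 1018.

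Medians over the plates of the other lists were 729 CPM for PRC2 subunits, 671 for PRC1 subunits, 59.6 for H3K27 demethylases, 703 for quiescence genes, 1182 for erythroid, 528 for neutrophil, 1028 for monocyte and dendritic, 179 for T and NK cell, 63.4 for mast cell, 111.3 for endothelial and stromal, 990 for interferon, 769 for immediate early, 860 for lineage transcription factors, 303 for Hox, 169 for developmental transcription factors, 10405 for housekeeping and 352 for sex-linked genes. Of 28 pairs of lists with enough UMIs, 4 had one sign of Spearman's rho in every plate, which is near the 12.5% given by chance. The pairs below are therefore described only. Ranked by the weakest plate, the monocyte and housekeeping lists came first, with a median of -0.0561 (-0.00788 without thinning, with both signs over the plates). Medians were larger in size for the housekeeping list with the immediate early list (-0.0730) and with lineage transcription factors (0.0697).

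Leiden clustering gave 6 clusters, and 99.9% of cells lay in a cluster made mostly of their own plate. Plates 350W and 351W were a cluster each, led by Tmem185a, Pip4p2, Spty2d1, Tbxa2r and Slc39a6 in 350W and by Hdac11, Senp7, Fen1, Birc2 and Pithd1 in 351W, with Tmem185a in 94.7% of cells of its cluster. In 352W, the immunoglobulin genes Iglc1, Iglv1 and Igha with Jchain and 2010309G21Rik led a cluster of 142 cells (84.0% of the plate), and Hist1h2af, Hist1h2ap, Hist1h2aa, Hist3h2a and Trim17 led one of 27 cells. Hist3h2a and Trim17 had the same 2541 CPM in that cluster and may share reads. In 353W, Fam173b, Rbm48, Bax, Poc5 and Shprh led a cluster of 156 cells, 155 of them from that plate, and Ctsg, H2afx, Ncapd2, Mpo and Hist1h2ap led one of 20 cells. No cluster had 3 fixed markers of a type among its leading genes, so none was named.

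For lower Bach2 in KO cells, counts thinned to equal totals gave -3.33 (SE 0.250). Random thinning of summed counts keeps the expected fold change, so this value cannot decide on lower depth. Median UMIs per kept KO cell were 0.725 to 0.896 of the WT value. Unscaled Bach2 counts were 117, 110, 60 and 137 in WT cells and 7, 9, 1 and 14 in KO cells of 350W to 353W. A fall of that size in every plate argues against lower depth per cell as the sole cause. With only cells of at least 1000 UMIs, the log2 fold change was -3.33 (SE 0.239). The same wells recurring in every plate were argued against by a mean correlation between plates of 0.00235, against 0.261 for the highest gene under shuffled wells. Lymphoid cells among the WT cells were tested by 5 lymphoid genes without immunoglobulins, which had a median of -0.114 (SD 0.269). These genes did not fall as far as Bach2, but a minority of lymphoid cells need not lower them that far. In 350W and 351W the whole lymphoid list was at 154 and 208 CPM in WT cells and 162 and 202 in KO cells. Bach2 counts there were 117 and 110 in WT cells and 7 and 9 in KO cells. These values argue against lymphoid cells as the cause in 350W and 351W. In 352W and 353W the list was at 8067 and 2412 in WT cells and 5706 and 1378 in KO cells, so lymphoid cells stay open there. A steady trend over well numbers was argued against by later against earlier wells, with 0.124 (SE 0.192) within WT cells and 0.473 (SE 0.716) within KO cells. Neither value was in the direction of the fall, but a step between the ranges of wells cannot be told apart from genotype. A broader test of well position, set before the results were seen, used the same values. It could not decide, because the SE within KO cells was too large. A biological effect of Phf19 loss stays open and untested.

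For Nim1k, with an edgeR adjusted p of 0.104 between KO and WT cells, the correlation between plates was 0.688, with 33, 35, 37 and 43 UMIs in well 78 of the 4 plates. For the 6 genes called between KO and WT cells, 1 of 8 splits that swap genotype within plates gave as many, the real one, and the highest of the others was 1, with too few splits for a share under 0.05. Cells with Xist alone and cells with Y-linked genes alone numbered 5 and 37 in WT cells and 0 and 30 in KO cells of 350W, 12 and 34 against 6 and 38 in 351W, 22 and 19 against 17 and 13 in 352W, and 21 and 16 against 18 and 21 in 353W. Cells with both numbered 5, 8, 19 and 37 in WT cells and 2, 2, 12 and 29 in KO cells of plates 350W, 351W, 352W and 353W.

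For the larger number of regions in KO lists, a difference in how many weak regions pass the caller's threshold stays open. Regions of a KO list absent from both control lists had lower median scores than shared ones (gaps of -42.2 in KO 1 and -27.8 in KO 2), but so did unshared regions of the control lists (-32.8 and -8.01), so these gaps decide nothing. Regions of both replicate 1 lists (980) outnumbered the KO-specific ones (462), consistent with a difference between replicate numbers, and did so at equal list lengths too (232 against 92). The short control list stays open, since the ratio without it was 1.30. The highest score in control 1 belonged to a region present in all lists, of 1398 bp on chromosome 2 from 98506243 to 98507640 (mm9), 24.0 times the median score of that list. Nearly the same interval ranked 2, 1 and 2 in control 2, KO 1 and KO 2, at 34.8, 19.6 and 32.2 times their median scores. Regions prone to artefactual signal were not filtered out, so such a score need not mean strong H3K27me3.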
